A study of Mus musculus with 10 samples.

How the data were processed

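RNA of ventricular cardiomyocytes and of whole hearts was hybridised to Affymetrix arrays as biotin-labelled cDNA, per the labels' protocols. RNA had been extracted with a Bio-Rad kit for fatty and fibrous tissue, no treatment was given, and 2 RNA samples were pooled for each array. The labels name an Ambion and an Affymetrix manual for the labelling of cardiomyocyte RNA and an Affymetrix manual alone for hearts, so a labelling batch could not be told apart from the tissue. The deposited values were log2 intensities of 35556 probe sets. RMA and Partek had been used, per the submitters' processing notes; their versions and settings are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes on the log2 scale. It compresses differences of dim probes and makes the arrays it treats together alike in distribution. The array medians differed between cardiomyocytes and hearts, so the sets were apparently normalized separately. Comparisons of KD with WT were therefore made within a tissue, and values across tissues are given under other scalings too. No detection calls or scanner values were used here.

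Genes were named from the platform annotation supplied with the probes. Of the probe sets 21789 had 1 gene symbol, 1621 had several and were not used, and 12146 were not listed with a gene. The reference table (GRCm38.p6) held the Entrez identifier of 21698, and 0 symbols changed through it. Of 999 genes with more than 1 probe set, the probe set with the highest mean over the 10 arrays was kept, which left 19938 genes. There was no filter on dim genes in the main analysis. The table had 0 columns that matched no sample. Groups were taken from the genotype and tissue labels.

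All 10 arrays were fitted in limma 3.58.1 under R 4.3.3 with 4 group means (lmFit, then eBayes with a trend on mean intensity; 6 residual and 6.81 prior degrees of freedom). The 4 contrasts were KD minus WT in cardiomyocytes (3 against 3), KD minus WT in hearts (2 against 2), the difference between those effects, and WT cardiomyocytes minus WT hearts. Tests were two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. A permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes were tested with limma's shared estimate of the spread. The 33 gene lists, 20 of pathways and 13 of cell type markers, held 687 entries, of which 620 were measured; 6 renamed genes were matched by a hand-written table of aliases after automatic matching of synonyms had proved wrong. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry.

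The groups, contrasts, gene tests, lists, alternative ways of processing and the rule for named genes were chosen before the data were examined. So were the list tests of KD against WT in each tissue. List tests of the difference between the KD effects, and of WT cardiomyocytes against WT hearts, were not in that plan. The rule took Slc18a3 and Chat, up to 10 genes per direction by fold among those past the threshold with non-overlapping arrays (filled from an unadjusted p under 0.01 and said not to pass), up to 4 members of each list with the smallest p, and 5 genes of the difference between tissues. Gene models, small RNAs and olfactory genes were not named, and the text gives a subset of the genes the rule took. The thymus, sex chromosome and blood checks were chosen after values had been seen.

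Alternatives were quantile normalization of all arrays, centring on array medians, a filter on dim genes, the mean of a gene's probe sets, fits on a single tissue, array weights, no intensity trend, robust eBayes, the replicate number as a block, other thresholds (an adjusted p of 0.1, a 1.5-fold change), and leaving out each array in turn. Removal of a loess trend (span 0.3) of the heart differences on mean intensity from the KD heart arrays was added as an alternative after seeing the data. The alternatives for the lists that differ between the KD effects were also run after seeing the data. Replicates of a group correlated at 0.988 to 0.992 in cardiomyocytes, 0.991 in WT hearts and 0.979 in KD hearts. The code was tested on simulated data with 200 changed genes in 10 runs. At 1.5-fold it recovered 75.2% of changed genes in cardiomyocytes and 42.7% in hearts, and at 2-fold 99.4% and 97.6%, with a mean of 13 and 9.7 false calls per run of 19938 genes. A simulated list shift of -0.2 was found in 10 of 10 runs in each tissue. Without a shift, 1 list in cardiomyocytes and 0 in hearts were called over these 10 runs of 33 lists; the simulated genes varied independently, which real genes of a list may not.

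Some rules of the checks on technical explanations were reworded after their outcome was known, and all wordings are counted here. The check of heart cell composition had 4 wordings. The first, over 4 marker lists, was undecided, and another that went against the explanation was not kept. One on dilution is reported as a separate and borderline test. The last, which is kept, applies the first rule to all fixed marker lists of other heart cells and of blood. It went against a lower share of cardiomyocytes taken up by all other cells. It cannot decide on a share taken up by blood or thymus RNA alone. The check for fewer macrophages had 2 wordings, of which the first favoured the explanation and the kept one is undecided. The check of a single cardiomyocyte array had 2 wordings, of which the first joined 2 lists and favoured the explanation, and the kept one treats each list alone.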

Results

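Transcript levels were measured on Affymetrix arrays in ventricular cardiomyocytes, the muscle cells of the heart chambers, and in whole hearts of wild-type (WT) mice and of mice with a knockdown (KD) of VAChT. VAChT, encoded by Slc18a3, is the vesicular acetylcholine transporter, which loads acetylcholine into secretory vesicles. There were 3 WT and 3 KD arrays of cardiomyocytes and 2 WT and 2 KD arrays of whole hearts. The labels described all mice as male, C57BL/6 and 3 months old. Each array held RNA pooled from 2 samples. Nothing beyond this pooling says that the arrays came from separate animals. The p-values of single genes thus measure the spread between these arrays, which may be partly technical. Those of camera set the genes of a list against the other genes, at a preset correlation of 0.01. Estimated correlations were larger for many lists, at 0.179 for fatty acid oxidation and 0.568 for the cell cycle. Small camera p-values therefore do not measure how well the arrays repeat a shift. The array medians lay between 5.82 and 5.93 on the log2 scale in cardiomyocytes and between 7.25 and 7.31 in hearts. The number of arrays limited the precision: the median 95% confidence interval of a KD minus WT difference reached 0.25 to either side in cardiomyocytes, a 1.19-fold difference, and 0.31 in hearts, a 1.24-fold difference.

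The first question was whether the targeted gene was lower in the KD arrays. Slc18a3 on chromosome 14 was not lower in the KD samples of either kind. In cardiomyocytes its log2 intensity was 6.06, 6.37 and 6.04 in the WT arrays and 6.22, 6.52 and 6.21 in the KD arrays. In hearts it was 7.34 and 7.72 in WT and 7.31 and 7.84 in KD. The difference was 0.16 (SE 0.16, 95% confidence interval -0.18 to 0.50) in cardiomyocytes, between 6.32 ± 0.17 in KD and 6.16 ± 0.19 in WT (SD, n = 3 each). In hearts it was 0.05 (SE 0.19, interval -0.37 to 0.46), between 7.58 ± 0.37 and 7.53 ± 0.27 (SD, n = 2 each). The adjusted p from limma was 1 in both. The heart difference turned to -0.14 without WT replicate 1 and -0.22 without KD replicate 2, where the remaining heart array of a genotype is assumed to vary like the other groups. Chat, the enzyme that makes acetylcholine, differed by 0.05 (SE 0.13, interval -0.24 to 0.34) in cardiomyocytes and by 0.03 (SE 0.16, interval -0.33 to 0.38) in hearts. The part of Slc18a3 altered in these mice and the position of its probes are not given in the sources used here. Slc18a3 also lay near the array medians of named genes, 6.186 to 6.274 in cardiomyocytes and 7.537 to 7.585 in hearts. Without detection calls it is not known whether its RNA was detected. A probe outside the altered part checks nothing, so these values neither bear out nor contradict the genotype labels.

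**Figure D1:**
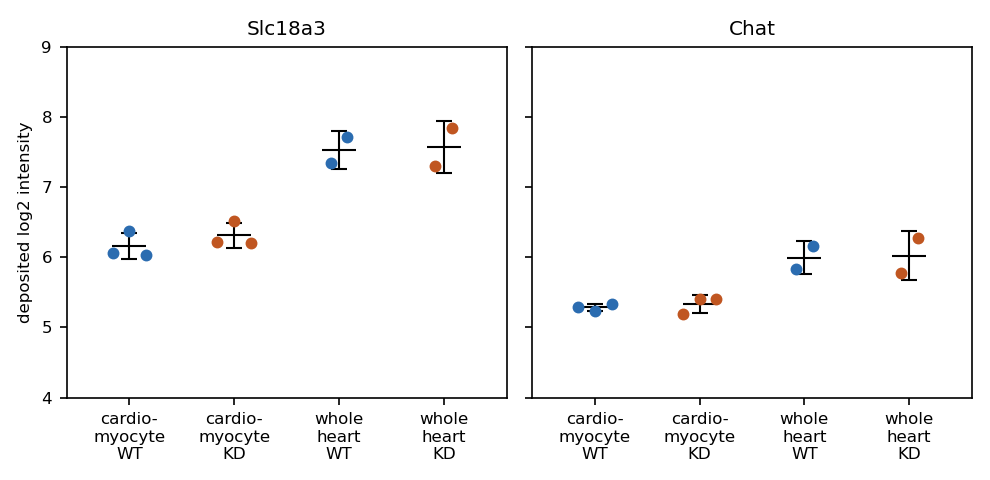
Deposited log2 intensity of Slc18a3 and Chat (y axis) in the 4 groups of arrays (x axis); each point is 1 array, and lines and bars show the mean and SD of a group (n = 3 for cardiomyocytes, n = 2 for hearts). The KD points of Slc18a3 lay at 6.21 to 6.52 in cardiomyocytes and at 7.31 and 7.84 in hearts, so the group means were 0.16 and 0.05 above those of WT; levels of the 2 kinds of sample are on separate scales.

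The comparison of KD with WT cardiomyocytes asked what the VAChT knockdown genotype goes with in the muscle cells themselves. By camera at its preset correlation, marker genes of macrophages and genes of the interferon response lay lower as groups in the KD cells, and genes of the circadian clock and of oxidative phosphorylation slightly higher; with an estimated correlation none of these calls held (adjusted p 0.497, 0.63, 0.497 and 0.54). Of the 16 macrophage markers 15 were lower in KD, with a median difference of -0.24, and of the 23 interferon response genes 21 were lower, with a median of -0.29; without WT replicate 3 these medians were -0.09 and 0.02. Of the 18 clock genes 14 were higher, with a median of 0.10, and of the 33 respiratory chain genes 29 were higher, with a median of 0.07. No single gene passed the threshold.

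The macrophage markers with the smallest p included C1qc and C1qb, chains of the complement component C1q. C1qc was 5.22 ± 0.07 in KD and 5.69 ± 0.34 in WT (SD, n = 3 each), a difference of -0.46 (SE 0.15). Both of these means lay below the cardiomyocyte array medians of 5.82 to 5.93, so the C1qc signal was dim. C1qb differed by -0.54 (SE 0.26). Among the interferon response genes, Stat2, which carries the type I interferon signal to the nucleus, differed by -0.45 (SE 0.17), and Tap1, a transporter of antigen peptides, by -0.44 (SE 0.19). None of the members of either list passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 1.7e-07 for each of the lists, and 0.497 for the macrophage list and 0.63 for the interferon list with an estimated correlation. The spread lay mostly in WT: relative to the WT mean, the interferon list averaged 0.64 in WT replicate 3 and -0.51 in WT replicate 2, with the KD arrays between -0.37 and -0.24. The interferon median was -0.58 without WT replicate 2. Without WT replicate 3 it was 0.02, with a camera adjusted p of 0.93, and the macrophage median was -0.09, with an adjusted p of 0.014.

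The circadian list held Per2, a repressor of the clock, at a difference of 0.33 (SE 0.12), and Dbp, a clock-controlled transcription factor, at 0.35 (SE 0.13). Its camera adjusted p was 0.0039, with an adjusted p of 0.497 with an estimated correlation. All 3 KD arrays lay above all 3 WT arrays in the mean of this list, at 0.07 to 0.15 against -0.04 to 0.04. Without KD replicate 1 its adjusted p was 0.06. In the oxidative phosphorylation list, Cox8b, a subunit of cytochrome c oxidase, differed by 0.21 (0.06 without WT replicate 3) and Ndufs4, a subunit of complex I, by 0.18. The camera adjusted p of that list was 0.0023, with an adjusted p of 0.54 with an estimated correlation. It was 0.2 without WT replicate 3 (median 0.04) and 0.086 without KD replicate 1 (median 0.05). No member of either list passed over all genes or adjusted over the list alone.

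Another 2 lists lay lower in the KD cardiomyocytes. Of 22 genes of ion channels and gap junctions 18 were lower, with a median of -0.09, among them the T-type calcium channel gene Cacna1h at -0.44 (SE 0.15) and the potassium channel gene Kcna4 at -0.26 (SE 0.11). Camera gave an adjusted p of 0.0041, and 0.497 with an estimated correlation; without WT replicate 2 or KD replicate 2 the adjusted p was 0.092 (median -0.05) or 0.25 (-0.07). The median was -0.14 without WT replicate 3 and -0.05 without KD replicate 3, still called. Of 26 inflammation genes 22 were lower, with a median of -0.06, among them the adaptor gene Myd88 at -0.27 and Socs3, an inhibitor of cytokine signalling, at -0.23. Camera gave an adjusted p of 0.014, and 0.497 with an estimated correlation. That call was lost without WT replicate 1 (adjusted p 0.065, median -0.11), WT replicate 3 (0.53, -0.06) or KD replicate 1 (0.11, -0.035), and with a filter on dim genes (0.08, -0.12), and the median was -0.12 without WT replicate 2 or KD replicate 2, where it was kept. No member of either list passed over all genes or adjusted over the list alone.

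**Figure D2:**
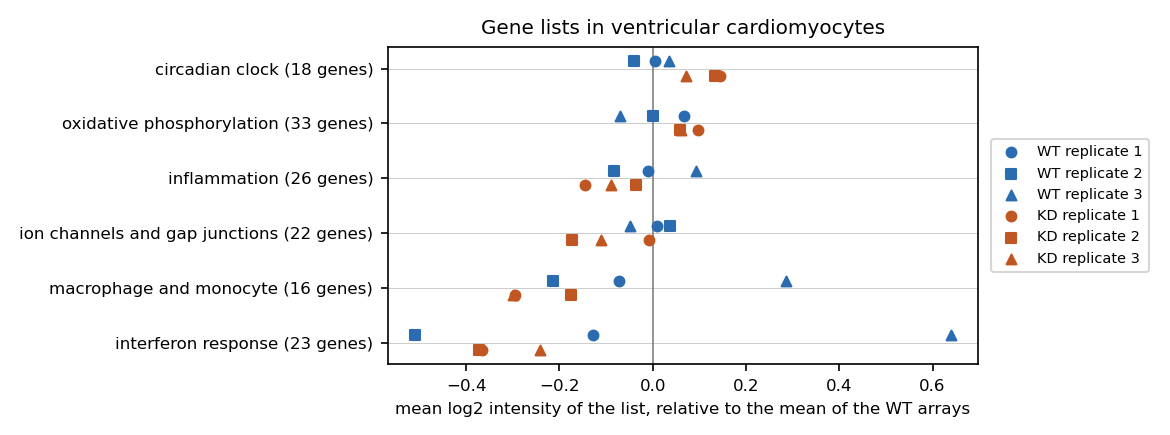
Mean log2 intensity of the 6 gene lists called in cardiomyocytes, relative to the mean of the WT arrays (x axis), with a line for each list (y axis) and a point for each array. The WT arrays of the interferon list spread from -0.51 to 0.64, around the KD arrays, and the circadian list is the one among the 6 whose KD and WT arrays do not overlap.

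Other lists tied to the heart or to acetylcholine were not called in cardiomyocytes. Cholinergic signalling genes had a median of 0.03, with 12 of 20 higher and a camera adjusted p of 0.98; its member Chrna5, a nicotinic receptor subunit, differed by -0.29 (SE 0.09). The fatty acid oxidation list had a median of -0.03 (camera adjusted p 0.37), but was called lower with array weights (median -0.05, adjusted p 0.044) and without KD replicate 1 (-0.08, 0.00085), and the sarcomere list a median of 0 (camera adjusted p 1). Among the lists not called, the smallest camera adjusted p was 0.16, for the unfolded protein response, which was called lower with array weights (0.013), without WT replicate 2 (0.002) and without KD replicate 1 (0.014). Without WT replicate 2 the fibroblast (median -0.20, adjusted p 1.3e-05) and endothelial lists (-0.06, 0.023) were called lower, and without WT replicate 3 the atrial list (-0.315, 2.7e-05). Immediate early genes were called higher without WT replicate 1 (0.12, 0.023) and lower without KD replicate 2 (-0.07, 0.032), and matrix genes higher without KD replicate 1 (0.10, 0.014). Ccn2, a secreted matricellular protein gene held by the fetal gene and extracellular matrix lists, passed adjusted over the list alone in both, at 11.18 ± 0.25 in KD and 10.68 ± 0.06 in WT (SD, n = 3 each; difference 0.50, SE 0.12).

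Of 42 single genes taken for cardiomyocytes, 17 had a difference that shrank by over 1.5 times or turned with 1 array left out. The single genes with the highest differences among those with non-overlapping arrays and an unadjusted p under 0.01 did not pass, with a limma adjusted p of 1 each. The highest were Cd59a, an inhibitor of complement attack, at 1.04 (SE 0.25), Zbtb16, a transcription factor, at 0.94 (SE 0.28), and Igsf23 at 0.84 (SE 0.17). Cd59b, a close paralog of Cd59a whose signal may not be separable from it, was at 0.72 (SE 0.19). Mrpl20, a mitochondrial ribosomal protein gene, was at 0.71 and Shld1 at 0.63. The lowest were Xlr at -0.76 (SE 0.16), Scd4, a stearoyl-CoA desaturase gene, at -0.68 (SE 0.21), and Lyz1, a lysozyme gene, at -0.65 (SE 0.18). Trap1, a mitochondrial chaperone gene, was at -0.48 (SE 0.15).

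In the limma fit, 0 of 19938 genes passed between KD and WT cardiomyocytes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 419 genes, 197 higher and 222 lower, where 997 would come by chance. The 3 KD arrays lay entirely above or below the 3 WT arrays in 1238 genes (6.2%; chance gives 10%). Camera called 6 of 33 lists, camera with an estimated correlation 0 (lowest adjusted p 0.497) and fry 0 (lowest 0.847; 0.99 for change in either direction).

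Whole hearts were compared in the same way, to ask what the genotype goes with in the intact organ, where nerves, vessels, blood and connective tissue add to the RNA. Genes of fatty acid oxidation and oxidative phosphorylation lay lower as groups in the KD hearts. All 29 measured fatty acid oxidation genes were lower, with a median of -0.29, and 31 of 33 oxidative phosphorylation genes were lower, with a median of -0.20. With a trend of the differences on intensity removed these medians were -0.18 and -0.07, both still called, while the calls of glycolysis and sarcomere genes were lost. Genes of the cell cycle and of blood lay higher, with medians of 0.34 (25 of 25 genes) and 0.66 (4 of 4 genes), calls lost with an estimated correlation (adjusted p 0.214 and 0.115). The cell cycle median was 0.11 without KD replicate 1 and the blood median 0.39 without WT replicate 1. KD heart replicate 1 stood apart from the other 3 heart arrays: thymocyte genes were higher there by a median of 4.17 on the log2 scale, and T cell genes by 2.50. No single gene passed the threshold.

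The fatty acid oxidation genes with the smallest p were Hadhb, a subunit of the mitochondrial trifunctional protein, and the electron transfer genes Etfa and Etfdh. Hadhb was 12.77 ± 0.21 in KD and 13.22 ± 0.17 in WT (SD, n = 2 each), a difference of -0.45 (SE 0.13). Etfa differed by -0.51 (SE 0.16) and Etfdh by -0.46 (SE 0.15). Both KD arrays lay below both WT arrays in the list mean, at -0.32 and -0.25 relative to the WT mean. Camera gave an adjusted p of 9.6e-18, and 0.0498 with an estimated correlation. In the oxidative phosphorylation list, Uqcrfs1, the Rieske subunit of complex III, was 10.31 ± 0.03 in KD and 10.77 ± 0.14 in WT (SD, n = 2 each), and Sdhd, a subunit of complex II, differed by -0.41. Camera gave this list an adjusted p of 9.2e-13, and 0.0498 with an estimated correlation. Glycolysis and glucose use genes were lower in 18 of 23, with a median of -0.18, among them Pdhb, a subunit of pyruvate dehydrogenase, at -0.39, and Pfkfb2, a regulator of glycolysis, at -0.44. Camera gave an adjusted p of 2.1e-06, and 0.0896 with an estimated correlation. The glycolysis median was -0.08 without WT replicate 1 and -0.29 without WT replicate 2. With the trend on intensity removed, the median and camera adjusted p were -0.06 and 0.28 for glycolysis, -0.07 and 0.041 for oxidative phosphorylation, and -0.18 and 6.9e-08 for fatty acid oxidation. KD replicate 1, whose thymocyte genes were higher, and KD replicate 2 lay close together in oxidative phosphorylation too, at -0.22 and -0.17. No member of these 3 lists passed over all genes or adjusted over the list alone.

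Calcium handling genes were lower in 17 of 21, with a median of -0.18 and a camera adjusted p of 2.1e-06 (0.0498 as an adjusted p with an estimated correlation). Among them S100a1, a calcium sensor, and Casq2, the calcium store protein of the sarcoplasmic reticulum, each differed by -0.32. The calcium handling median was -0.28 without WT replicate 2 and -0.27 without KD replicate 2. Sarcomere genes were lower in 20 of 23, with a median of -0.12 and a camera adjusted p of 4.9e-05, and an adjusted p of 0.214 with an estimated correlation. With the trend on intensity removed, an alternative chosen after seeing the data, the sarcomere median turned to 0.007 (adjusted p 0.76), and the calcium handling median was -0.09 (0.012). Mybpc3, a thick filament protein gene, differed by -0.26 and Tpm1, a tropomyosin gene, by -0.22. Without KD replicate 1, the array with the thymocyte signal, the sarcomere median was -0.03 and its adjusted p 0.15; without KD replicate 2 the median was -0.20. Ion channel and gap junction genes were lower in 18 of 22, with a median of -0.10 and a camera adjusted p of 0.0072, and an adjusted p of 0.214 with an estimated correlation. That adjusted p was 0.061 without WT replicate 1 (median -0.05), 0.16 without KD replicate 1 (median -0.006) and 0.11 with the filter on dim genes; without KD replicate 2 the median was -0.16. Adrenergic and G protein signalling genes were lower in 15 of 22, with a median of -0.08 and a camera adjusted p of 0.017, and an adjusted p of 0.152 with an estimated correlation. Here Rgs4 and Adcy6, which act on receptor signalling, differed by -0.37 and -0.42; the adjusted p was 0.065 without WT replicate 2 (median -0.15), 0.29 without KD replicate 2 (median -0.17) and 0.19 with the filter. With the intensity trend removed the adrenergic adjusted p was 0.14. The adrenergic median was -0.05 without WT replicate 1 and -0.02 without KD replicate 1. None of the members passed over all genes or adjusted over the list alone.

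Atrial marker genes had a median of -0.66, with 7 of 9 lower and a camera adjusted p of 0.00041, and an adjusted p of 0.214 with an estimated correlation. Bmp10, a growth factor gene of the atria, was 9.57 and 9.52 in WT and 9.21 and 8.05 in KD, and Nppa, the atrial natriuretic peptide gene, was 13.24 and 13.04 in WT and 13 and 11.69 in KD (difference of means -0.79, SE 0.43). Without KD replicate 2 the atrial median was -0.25 and its adjusted p 0.1, without KD replicate 1 the median was -1.03, and with the filter on dim genes the adjusted p was 0.13 (median -0.43). The atrial list shares Nppa, Myl4 and Myl7 with the fetal and hypertrophy list and Sln with the calcium handling list, so these are not separate results. Fetal and hypertrophy genes had a median of -0.09, with 17 of 23 lower, among them Nppb at -0.80 (SE 0.37). The camera adjusted p of the fetal list was 0.033, and the adjusted p 0.235 with an estimated correlation. That call was lost without WT replicate 2 (adjusted p 0.33, median -0.04), KD replicate 1 (0.16, at a median of 0.01) or KD replicate 2 (0.11, median -0.20), and with the filter on dim genes (0.16), quantile normalization (0.33), centring on array medians (0.05) or the intensity trend removed (0.57). Vegfa, a growth factor gene for vessels, was 9.98 ± 0.22 in KD and 10.57 ± 0.11 in WT (SD, n = 2 each; difference -0.60, SE 0.14); its limma adjusted p over all genes was 0.87, and it passed adjusted over the list alone in the neurotrophic list, which was not called. Unfolded protein response genes had a median of -0.11, with 14 of 20 lower and a camera adjusted p of 0.013, and an adjusted p of 0.429 with an estimated correlation. The adjusted p was 0.97 without KD replicate 2 (median -0.04), 0.16 with the filter, 0.09 after quantile normalization and 0.37 with the intensity trend removed; without KD replicate 1 the median was -0.23.

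Matrix genes and markers of fibroblasts, vessel cells and adipocytes also lay lower in KD, while markers of macrophages, Schwann cells and autonomic neurons were not called. Extracellular matrix genes were lower in 24 of 29 (median -0.12, camera adjusted p 1.6e-05, and an adjusted p of 0.214 with an estimated correlation). Col3a1, a fibrillar collagen gene, differed by -0.56 (SE 0.17) and Eln, the elastin gene, by -0.45. Fibroblast markers were lower in 14 of 15 (median -0.18, camera adjusted p 0.0017, and an adjusted p of 0.342 with an estimated correlation). The exception was Thy1 at 1.26, a gene that thymocytes also express. Endothelial markers were lower in 14 of 15 (median -0.17, camera adjusted p 0.00013, and an adjusted p of 0.331 with an estimated correlation), with the lipid carrier gene Fabp4 at -0.49; the median was -0.11 without WT replicate 1 and -0.27 without WT replicate 2. Smooth muscle and pericyte markers were lower in 10 of 12 (median -0.13, camera adjusted p 0.0073, and an adjusted p of 0.342 with an estimated correlation), with the pericyte gene Rgs5 at -0.39. Adipocyte markers were lower in 11 of 11 (median -0.29, camera adjusted p 7.8e-06, and an adjusted p of 0.0498 with an estimated correlation), with Car3 at -0.52; the median was -0.18 without WT replicate 1. The fibroblast adjusted p was 0.29 without KD replicate 2 and 0.088 with the filter on dim genes, and that of smooth muscle 0.14 without KD replicate 1 (median -0.07) and 0.073 with the filter. With the intensity trend removed the adjusted p was 0.061 for endothelial (median -0.11) and 0.1 for smooth muscle markers (median -0.09). No member of these 5 lists passed over all genes or adjusted over the list alone.

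Cell cycle genes were higher in 25 of 25, with a camera adjusted p of 3.7e-15, and an adjusted p of 0.214 with an estimated correlation. Mki67, a proliferation marker, was 8.44 ± 1.00 in KD and 7.29 ± 0.23 in WT (SD, n = 2 each), and Ccnb2, a mitotic cyclin gene, differed by 0.70 (SE 0.21). Relative to the WT mean the list averaged 0.93 in KD replicate 1 and 0.08 in KD replicate 2. Without KD replicate 1 the median was 0.11 and the camera adjusted p 0.45, and without KD replicate 2 the median was 0.64. Lymphocyte markers had a median of 0.41, with 8 of 12 higher, a camera adjusted p of 0.016, and an adjusted p of 0.526 with an estimated correlation. Without KD replicate 1 their median was -0.12, and the list was then called lower, with an adjusted p of 0.0014; without WT replicate 1 the adjusted p was 0.31 (median 0.23), and with the filter on dim genes 0.21. In a fit of the heart arrays alone it was 0.077, and without KD replicate 2 the median was 0.95. The list of lung and thymus genes had a median of 0.08 and a mean of 0.68, with 9 of 12 higher, a camera adjusted p of 0.027, and an adjusted p of 0.214 with an estimated correlation. That adjusted p was 0.16 without KD replicate 1 (median 0.17), 0.73 without WT replicate 1 (median 0.03), 0.098 in the fit of heart arrays alone and 0.061 with the intensity trend removed (median 0.03); the median was 0.15 without WT replicate 2 and 0.02 without KD replicate 2. Dntt, Rag1, Rag2 and Themis, thymocyte genes, passed adjusted over the list alone, as did the airway gene Scgb1a1 at -1.06 (SE 0.38), which was -1.98 without WT replicate 1. Rag1, a gene for antigen receptor assembly named after its values were seen, was 11.68 in KD replicate 1 and 6.51 to 6.73 in the other 3 heart arrays; Dntt was 9.64 against 5.58 to 6.19.

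**Figure D3:**
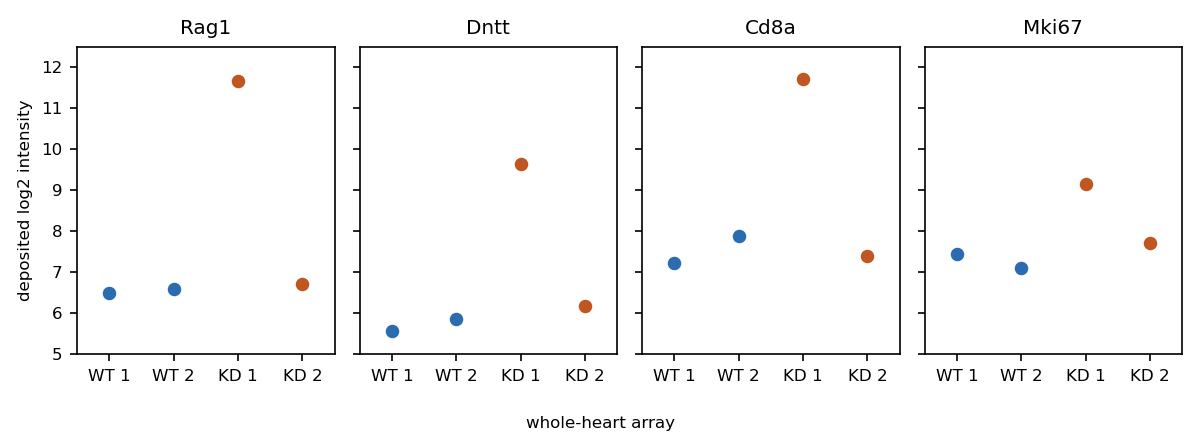
Deposited log2 intensity (y axis) of Rag1, Dntt, Cd8a and Mki67 in the 4 whole heart arrays (x axis), with a point for each array. KD replicate 1 lies above the other 3 arrays in each gene, for Cd8a at 11.73 against 7.22 to 7.90.

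Blood genes, measured by the red cell genes Alas2 and Slc4a1 and the platelet genes Pf4 and Ppbp, were higher in KD in 4 of 4, with a camera adjusted p of 1.6e-05, and an adjusted p of 0.115 with an estimated correlation. Alas2, the first enzyme of heme synthesis in red cells, was 11.26 and 11.97 in WT and 12.24 and 12.51 in KD, and Slc4a1, the red cell anion exchanger, was 9.06 ± 0.04 in KD and 8.51 ± 0.22 in WT (SD, n = 2 each). Both passed adjusted over the list alone and not over all genes. Pf4 differed by 0.32 (SE 0.27) and Ppbp by 1.11 (SE 0.60), which without WT replicate 1 were -0.03 and 0.38; Alas2 was then 0.41. The list median was 0.39 without WT replicate 1 and 0.91 without WT replicate 2. The list was higher in both KD arrays, at 0.55 and 0.83 relative to the WT mean, with the WT arrays at -0.40 and 0.40.

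Among the heart lists not called, cholinergic signalling genes had a median of 0.05, with 13 of 20 higher and a camera adjusted p of 0.4. Chrm2, the main muscarinic receptor of the heart, differed by -0.27, and Colq, the collagen tail of acetylcholinesterase, by 0.41. Macrophage markers had a median of 0.01 (camera adjusted p 0.88), interferon response genes of -0.11 (0.24, but 0.023 in the fit of heart arrays alone and 0.033 without KD replicate 1), inflammation genes of 0.04 (0.85), circadian genes of 0.09 (0.18), antioxidant genes of -0.03 (0.16, but 0.037 without WT replicate 1) and heat shock genes of -0.12 (0.051). Immediate early genes had a median of 0.06 (0.24), autophagy genes of -0.01 (0.27, but 0.032 without WT replicate 1) and neurotrophic genes of 0.05 (0.92). Circadian genes were called higher after quantile normalization (adjusted p 0.04), with the filter on dim genes (0.024) and with the intensity trend removed (0.019), at medians of 0.12, 0.09 and 0.14, and their median was -0.07 without KD replicate 2. The medians were -0.11 for mesothelial (0.22), 0.07 for Schwann cell (0.39), 0.01 for autonomic neuron (0.92) and 0.08 for skeletal muscle markers (0.24).

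**Figure D4:**
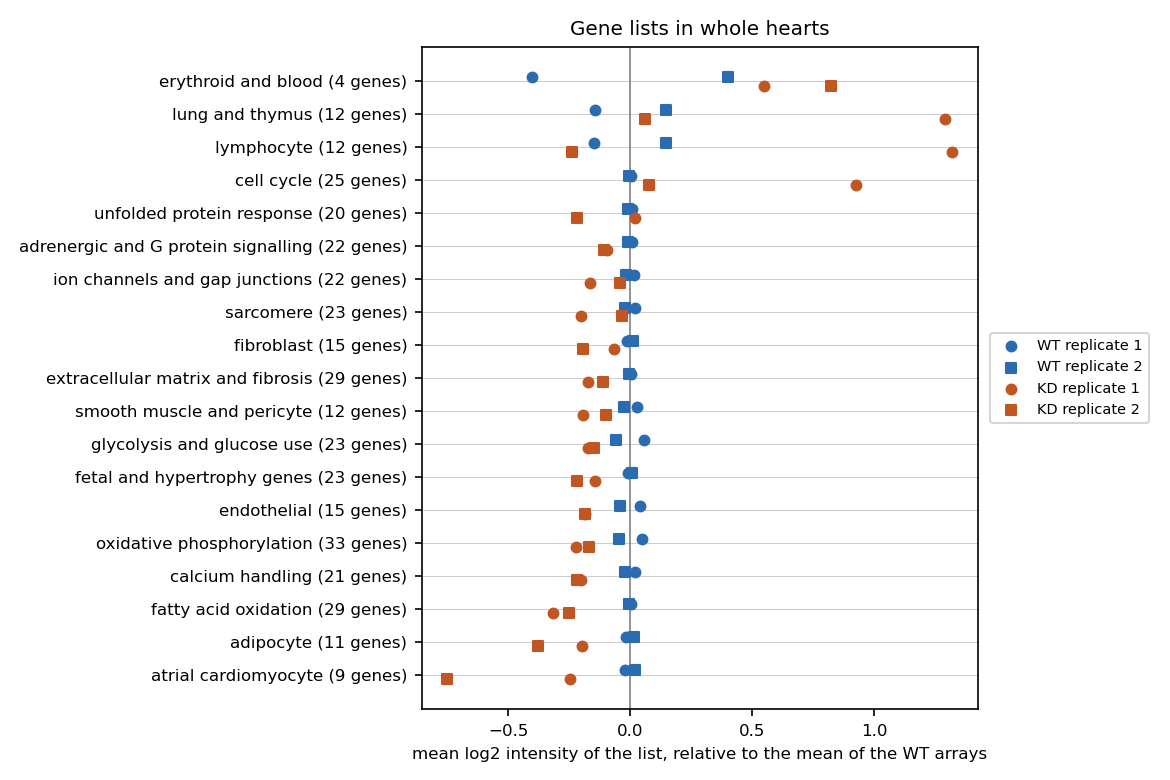
Mean log2 intensity of the 19 gene lists called in whole hearts, relative to the mean of the WT arrays (x axis), with a line for each list (y axis) and a point for each array. In the cell cycle and lymphocyte lists KD replicate 1 lies at 0.93 and 1.32 and KD replicate 2 at 0.08 and -0.24, while in the fatty acid oxidation list both KD arrays lie below the WT arrays.

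The genes with the highest and lowest differences in hearts, taken from those with non-overlapping arrays and an unadjusted p under 0.01, had limma adjusted p values of 0.71 to 0.95 and did not pass. Highest was Dntt at 2.19 (SE 0.70), in which KD replicate 1 stood apart, then the histone gene H4c6 at 1.38 (SE 0.40; 0.58 without KD replicate 1), Hal, the first enzyme of histidine breakdown, at 1.23 (SE 0.30; 0.66 without WT replicate 1), and the platelet receptor gene Clec1b at 1.17 (SE 0.28; 0.69 without WT replicate 1). Lowest after Bmp10 and Bpifb1 were Mylk4, a myosin light chain kinase family gene, at -0.72 (SE 0.15), and Etfrf1, a regulator of the electron transfer flavoprotein, at -0.71 (SE 0.15; 8.23 ± 0.10 in KD and 8.94 ± 0.14 in WT, SD, n = 2 each). Angpt1, a vessel growth factor gene, was at -0.67 (SE 0.19), and Cacna2d1, a calcium channel subunit gene, at -0.64 (SE 0.18).

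Of 67 single genes taken for hearts, 48 had a difference that shrank by over 1.5 times or turned with 1 of the 4 arrays left out. In the limma fit 0 of 19938 genes passed between KD and WT hearts, with a smallest adjusted p of 0.713. At an unadjusted p under 0.05 there were 982 genes, 486 higher and 496 lower, where chance gives 997, and the arrays did not overlap in 5894 genes (29.6%; chance gives 33.3%). Without KD replicate 2, which leaves KD replicate 1 alone and assumes that it varies like the other groups, 303 genes passed, 295 of them higher; without WT replicate 1 there were 2 and without KD replicate 1 there was 1. Camera called 19 of 33 lists, 4 higher and 15 lower, and 12 with the intensity trend removed, 4 higher and 8 lower. With an estimated correlation 4 remained, those of fatty acid oxidation, oxidative phosphorylation, calcium handling and adipocytes, and fry called 0 (lowest adjusted p 0.0607; 0.051 for change in either direction).

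The difference between the KD effects in cardiomyocytes and in hearts was tested next. Genes of fatty acid oxidation and oxidative phosphorylation lay lower in KD hearts relative to WT than they did in KD cardiomyocytes, and cell cycle and blood genes lay higher. The median difference, cardiomyocyte effect minus heart effect, was 0.27 for oxidative phosphorylation (camera adjusted p 1.9e-14), 0.24 for fatty acid oxidation (9.5e-10), 0.19 for glycolysis (1.3e-05) and 0.19 for calcium handling (0.00077). It was -0.43 for the cell cycle (4.4e-12), where KD heart replicate 1 held the thymocyte signal, -0.68 for the blood list of red cell and platelet genes (7.4e-05) and -0.25 for macrophage markers (0.0017). With the intensity trend removed from the hearts, the difference was 0.155 for oxidative phosphorylation (0.00038) and 0.12 for fatty acid oxidation (0.0011), while the calls of glycolysis (0.08, adjusted p 0.18) and calcium handling (0.08, 0.15) were lost. Without KD heart replicate 1 the cell cycle difference was -0.135 (0.22), and without WT cardiomyocyte replicate 3 that of macrophage markers was -0.10 (0.057). The blood difference was -0.325 without WT heart replicate 1 and -1.04 without WT heart replicate 2. Camera called 13 of 33 lists, 7 with the intensity trend removed, and 0 with an estimated correlation, where the lowest adjusted p was 0.127; fry called 0 (lowest 0.137; 0.11 for change in either direction).

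Among single genes 0 of 19938 passed the limma test of this difference (smallest adjusted p 0.999), with 696 at an unadjusted p under 0.05. The 5 with the smallest p were the histone genes H4c14 at -1.02 (SE 0.21) and H4c3 at -1.15 (SE 0.25), Mns1 at -0.80 (SE 0.17), Ccn2 at 0.85 (SE 0.19) and Ckap2l, a mitotic spindle gene, at -0.65 (SE 0.14). Of these Ccn2 passed adjusted over the list alone, in the fetal gene and extracellular matrix lists. Without KD heart replicate 2, 237 genes passed, 235 of them lower. Across genes, which are not independent replicates, the KD effects in cardiomyocytes and hearts had a Pearson correlation of -0.022 and a Spearman correlation of -0.018. Over 30 relabellings of the arrays, the real one included, the Pearson value ran from -0.148 to 0.208 and was as large in size in 29. At an unadjusted p under 0.05 in both there were 28 genes, where 20.6 would be shared by chance, and 14 had the same sign.

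WT cardiomyocytes were compared with WT hearts to describe what each kind of sample held. Muscle, mitochondrial and immediate early genes stood higher in the isolated cells relative to other genes, and genes of fibroblasts, macrophages and the extracellular matrix stood lower. With an estimated correlation camera kept its calls of oxidative phosphorylation (adjusted p 0.0499), calcium handling (0.0499) and heat shock genes (0.0379), and those of sarcomere and immediate early genes (0.0606 each), fatty acid oxidation (0.118), fibroblasts (0.477), macrophages (0.328) and matrix (0.405) were lost. The sets of arrays were apparently normalized separately and their labels name different labelling manuals, so tissue and batch cannot be told apart, and levels are given both as deposited and after quantile normalization of all 10 arrays. The median of all genes was -1.20 (cardiomyocytes minus hearts) as deposited and -0.004 after quantile normalization. The list calls above are on the deposited values. Calcium handling genes had a median of 0.67 above that of all genes as deposited, and of 0.15 after quantile normalization. On that scale 8 of 21 calcium handling genes were called higher and 2 lower, and 7 of 15 heat shock genes higher and 4 lower. Limma called 18175 genes as deposited, 772 higher in cardiomyocytes and 17403 lower, 11772 after quantile normalization (5944 higher, 5828 lower) and 12950 with each array centred on its median (8421 higher, 4529 lower). The arrays did not overlap in 18659 genes as deposited (93.6%; chance gives 20%).

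All 23 sarcomere genes lay above the all-gene median, with a list median of 1.12 above it, and 0.44 after quantile normalization. Tnni3, cardiac troponin I, was 1.04 higher in cardiomyocytes as deposited (1.63 after quantile normalization), and Ttn, the titin gene, 1.03 (1.59). Of 33 oxidative phosphorylation genes 30 lay above the all-gene median (list median 1.17 above it, and 0.48 after quantile normalization), as did 27 of 29 fatty acid oxidation genes (0.89 and 0.41). Immediate early genes, which respond within minutes to stimulation and to cell handling, lay above it in 27 of 28 (median 1.18, and 1.06 after quantile normalization): Fos was 9.35 ± 0.22 in cardiomyocytes and 7.12 ± 0.28 in hearts (SD, n = 3 and 2), Egr1 was 2.19 higher and Atf3, a stress-response gene, 3.26 higher. Heat shock genes had a median of 0.95 above it, and 0.30 after quantile normalization. Camera gave adjusted p values of 2.4e-24 for immediate early, 3.6e-15 for oxidative phosphorylation, 8.6e-13 for sarcomere, 1.6e-08 for fatty acid oxidation and 3.6e-07 for heat shock genes. These tests used the deposited values, on which the sets lay farther apart for dim than for bright probe sets. The 25th percentile was 4.474 to 4.512 in WT cardiomyocyte arrays and 5.996 and 6.014 in WT hearts. The 75th was 7.469 to 7.518 and 8.454 and 8.469. Bright lists may thus stand above the all-gene median in part through the scale, and no camera p is given for normalized values.

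Unless stated, list medians below are relative to the all-gene median (-1.20 as deposited) and single genes are as deposited. Fibroblast markers lay below the all-gene median in all 15, by a list median of -1.81 (-2.16 after quantile normalization), with the collagen genes Col1a1 at -3.00 and Col3a1 at -3.54 as deposited (cardiomyocytes minus hearts). Macrophage markers lay below it in 15 of 16 (median -2.13), with C1qc at -4.36, and the red cell and platelet genes of the blood list in 4 of 4 (median -2.41), with Alas2 at -5.98 (-5.09 after quantile normalization). Adipocyte and atrial markers had medians of -1.12 and -1.26, with Car3 at -6.11 and Bmp10 at -5.25; Adipoq, a hormone of fat cells, was at -4.44. Endothelial markers had a median of 0.02, with 8 of 15 above the all-gene median, which turned to a list median of -0.53 after quantile normalization. Vwf was at -3.01 and Pecam1 at -2.04 as deposited, and at -2.17 and -1.4 after quantile normalization. Camera gave adjusted p values of 0.0032 for macrophage, 0.0075 for fibroblast, 0.002 for extracellular matrix and 0.027 for mesothelial genes. It did not call the blood (0.22), adipocyte (0.12) or atrial lists (0.89, direction higher). The adjusted p of mesothelial genes was 0.35 with an estimated correlation. Camera called 15 lists (11 higher, 4 lower), 3 with an estimated correlation, and fry called 32. Because camera compares a list with other genes, its direction and the sign of the deposited median differed for 11 of the 15 called lists. Slc18a3 was at -1.37 as deposited and at -0.06 after quantile normalization, where it did not pass (adjusted p 0.79 by limma). Chat was at -0.71 as deposited and at 0.79 after quantile normalization.

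Genes of the sex chromosomes separated the hearts from the cardiomyocytes in both genotypes, though all samples were labelled male. Xist, the RNA that silences the inactive X chromosome of female cells, was at 9.77 to 10.35 in the 4 heart arrays, between the 91.8 and 95.3 percentiles of its array, and at 3.70 to 4.03 in the 6 cardiomyocyte arrays, between the 6.4 and 11.2 percentiles. The Y-linked gene Eif2s3y was at 3.68 to 4.14 in hearts (percentiles 1 to 1.8) and at 8.02 to 8.50 in cardiomyocytes (80.2 to 85.9). Uty, also Y-linked, was at 4.42 to 4.91 in hearts (3.2 to 4.9) and at 7.49 to 7.78 in cardiomyocytes (72.5 to 76.3). KD and WT arrays of a tissue did not differ in this respect, while every comparison across the tissues holds this difference too.

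**Figure D5:**
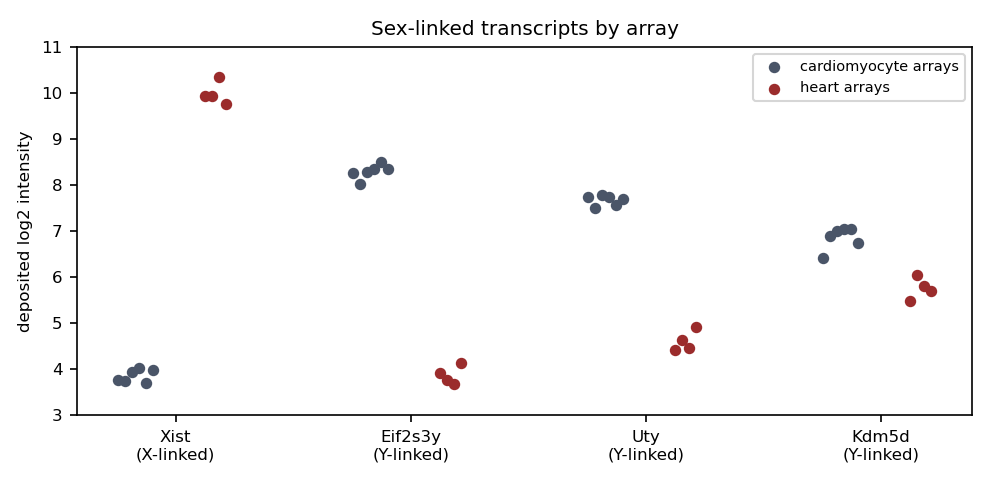
Deposited log2 intensity (y axis) of Xist and of Y-linked genes in the 6 cardiomyocyte and 4 whole heart arrays (x axis), with a point for each array. Xist lies at 9.77 to 10.35 in hearts and at 3.70 to 4.03 in cardiomyocytes, and Eif2s3y at 3.68 to 4.14 and at 8.02 to 8.50.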

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

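The removal of the intensity trend for the lists, the alternatives for lists that differ between the KD effects, and the tests of heart cell composition, of thymus RNA and of the sex-linked genes were chosen only after the results were seen, while those of intensity and of single KD heart arrays were chosen before.

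The difference between the KD effects in cardiomyocytes and hearts passed camera's test for 13 lists, with 0 at an estimated correlation. The median difference, cardiomyocyte effect minus heart effect, was 0.267 for oxidative phosphorylation, 0.241 for fatty acid oxidation, 0.193 for glycolysis and glucose use, 0.19 for calcium handling, 0.135 for the sarcomere and 0.164 for the extracellular matrix. It was 0.357 for atrial, 0.232 for adipocyte, 0.147 for endothelial and 0.137 for smooth muscle markers. It was -0.425 for the cell cycle, -0.248 for macrophage markers and -0.682 for the blood list of red cell and platelet genes. With the intensity trend removed from the hearts, 7 lists were called, and the sarcomere (0.013, adjusted p 0.95), glycolysis (0.079, 0.18), calcium handling (0.076, 0.15), atrial (0.313, 0.15), endothelial (0.109, 0.27) and smooth muscle differences (0.088, 0.23) lost their call. Without KD heart replicate 1 the sarcomere difference was 0.043 (0.19) and that of the cell cycle -0.135 (0.22), without KD heart replicate 2 the adipocyte difference was 0.122 (0.3) and the atrial one 0.052 (0.35), and without WT cardiomyocyte replicate 3 that of macrophage markers was -0.099 (0.057). Calls were also lost after quantile normalization for the sarcomere (0.11), atrial (0.11), endothelial (0.11) and smooth muscle lists (0.12), and with the filter on dim genes for the atrial (0.61), endothelial (0.085), smooth muscle (0.18) and adipocyte lists (0.084). With each array centred on its median the atrial adjusted p was 0.064. The atrial call was also lost without WT cardiomyocyte replicate 3 (0.155, adjusted p 0.64), KD cardiomyocyte replicate 1 (0.306, 0.15) or WT heart replicate 2 (0.474, 0.15). The endothelial call was lost without WT cardiomyocyte replicate 2 (0.087, 0.22), KD cardiomyocyte replicate 2 (0.121, 0.069), WT heart replicate 1 (0.139, 0.095) or KD heart replicate 2 (0.162, 0.095). The smooth muscle call was lost without WT cardiomyocyte replicate 2 (0.094, 0.25), KD cardiomyocyte replicate 2 (0.098, 0.15) or 3 (0.083, 0.12), WT heart replicate 1 (0.107, 0.11), or KD heart replicate 1 (0.084, 0.19) or 2 (0.174, 0.092).

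Fatty acid oxidation and oxidative phosphorylation genes lay lower in KD hearts by medians of -0.29 and -0.20. Bright genes were lower than dim ones in KD hearts: the median difference from WT was -0.073 in the 3988 brightest genes and 0.037 in the 3988 dimmest. After removal of this trend the fatty acid oxidation median was -0.179 (SE 0.034) and the oxidative phosphorylation median -0.069 (SE 0.031). This argues against the trend as the whole cause for the former. For the latter the trend is a candidate cause of most of the shift, by the bound of -0.1 set before. But the genes of that list are bright themselves, at a median intensity of 12.3. A real fall of bright genes would enter the trend and be removed with it. The shrinkage thus cannot tell a technical cause from a real one. The remainder exceeded 2 SE, with genes taken as independent, and kept its camera call (adjusted p 0.041). The list lay at the 0.1 percentile of 2000 lists matched on intensity. That percentile does not decide, since genes of random lists need not vary together. The interferon list, not called in hearts, lay at percentile 0. A single KD array was argued against, since the fatty acid oxidation median stayed at or below -0.244 with either left out. A lower share of cardiomyocytes with a higher share of all other cells was argued against. Adipocyte (-0.285, SE 0.06), endothelial (-0.17, SE 0.043) and smooth muscle markers (-0.126, SE 0.051) were lower and blood genes higher (0.657, SE 0.209). Fibroblast (-0.178, SE 0.132) and lymphocyte markers (0.405, SE 0.276) lay within 2 SE of 0, all SEs taking genes as independent. These values do not decide on a lower share through more blood or thymus RNA, which would lower the other heart markers too. In KD replicate 2 the lung and thymus list averaged 0.06 relative to the WT mean, and fatty acid oxidation still -0.252. This argues against thymus RNA as the cause in that array. The WT arrays lay at -0.4 and 0.4 in the blood list, and at 0.005 and -0.005 in fatty acid oxidation. With so few arrays this does not decide on blood. A test of dilution by blood or thymus RNA was borderline and does not decide either. The fatty acid oxidation list lay -0.121 (SE 0.06, or 2.01 SE) below 42 endothelial, fibroblast and smooth muscle markers. Their own median of -0.173 was 58.8% of the list's. Adipocyte markers, not among the 42, lay at -0.285 against -0.294 for that list. With the intensity trend removed the medians were -0.179 for that list, -0.178 for fibroblast, -0.108 for endothelial, -0.089 for smooth muscle and -0.284 for adipocyte markers. An effect of the genotype on cardiac metabolism stays open beside these explanations, as a hypothesis.

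Cell cycle and lymphocyte genes lay higher in KD hearts by camera at its preset correlation, but not with an estimated one (adjusted p 0.214 and 0.526); for lymphocytes this lay in KD replicate 1 alone, without which the list was called lower (median -0.115, adjusted p 0.0014). The intensity trend was argued against, since the cell cycle median was 0.324 (SE 0.088) after its removal, but without KD replicate 1 it was 0.106. A candidate source is thymus tissue in the RNA of that array: 4 thymocyte genes were higher there than in the other 3 heart arrays by a median of 4.17 (3.05 to 5.07) and 5 T cell genes by 2.50, with Rag1 at 11.68 and Cd8a at 11.73, while 5 B cell genes differed by 0.27 and 6 lung genes by -0.12. All of the thymocyte and T cell genes tested belong to the lung and thymus list or the lymphocyte list, both of them called higher. A difference between the animals, such as immune cells in the heart of that pool, was not tested.

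Xist was high and Y-linked genes low in all 4 heart arrays, and the reverse held in all 6 cardiomyocyte arrays, although every sample was labelled male. Separate normalization was argued against, because the percentile of Xist within its array differed by at least 80.7 points between any heart and any cardiomyocyte array. Female tissue in the heart samples is a candidate explanation: the median percentile of the Y-linked genes was at most 4.9 in a heart array. Since both genotypes show it, it leaves KD against WT within a tissue untouched, but sex, batch and tissue cannot be told apart in comparisons across tissues.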

How the results depend on the processing

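The removal of the intensity trend in hearts and all alternatives for lists that differ between the KD effects were chosen after the results were seen. Lists that lost their call in a tissue are given in the results, those of the difference between tissues among the results for a closer look; the cause was not tested unless stated. With an unadjusted p under 0.05 and at least a 1.5-fold difference, 21 genes were counted in cardiomyocytes, 168 in hearts and 167 for the difference between them, where the limma adjusted p gave 0 each. The lists called in cardiomyocytes numbered 0 with an estimated correlation and 0 with fry, and those in hearts 4 with an estimated correlation, 0 with fry, 12 with the intensity trend removed and 11 with the filter on dim genes, which leaves fewer members; these last 2 counts include the circadian list, not among the 19. The lists that differed between the KD effects numbered 13, 7 with the trend removed, 0 with an estimated correlation and 0 with fry. Genes called between WT cardiomyocytes and WT hearts numbered 11772 after quantile normalization and 8392 with the filter, which tests fewer genes. With a replicate block 1 gene passed in hearts, Clec1b (adjusted p 0.0352 by limma), the interferon list was newly called for the difference between tissues (median -0.223, adjusted p 0.029), and no other call changed. Deviations of same-numbered cardiomyocyte arrays correlated at 0.152, 0.131 and -0.052, so the numbers were not taken to pair them; those of heart arrays correlated at 0.234, which with 2 pairs leaves a shared effect of the number open. With single arrays left out, genes passing in hearts ran from 0 to 303 and for the difference between tissues from 0 to 237, the highest without heart KD replicate 2, and the correlation of effects from -0.092 to 0.073. In hearts Slc18a3 ran from -0.215 to 0.306, Chat from -0.219 to 0.275, Pf4 from -0.034 to 0.682, Cd4 from -0.032 to 2.652, Cd3g from -0.055 to 2.479 and Cd8a from -0.16 to 4.171. Chat in hearts was -0.013 after quantile normalization, -0.015 after centring and -0.021 with the trend removed. Between tissues Chat was 0.788 and 0.678 under the first 2, Slc18a3 was 0.015 after centring and -0.062 after quantile normalization, and Dpep2 was -0.008 with the mean of its probe sets. Of the values of single named genes under alternatives, 2064 kept their direction and side of the threshold, 25 newly passed it, 1 no longer passed and 15 reversed. Robust eBayes was not run for the lists, since camera has no such option. The number of arrays and dim signal, with no measure of background used here, limit what could be detected.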

Other observations

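The tests of fewer macrophages and of single cardiomyocyte arrays were chosen only after the results were seen, while the splits of the arrays and the test of genes near Slc18a3 were chosen before.

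By camera at its preset correlation, macrophage and interferon response genes lay lower in KD cardiomyocytes. With an estimated correlation neither call held (camera adjusted p 0.497 and 0.63). Fewer macrophages among the isolated KD cells may account for both shifts. Across the 6 cardiomyocyte arrays the means of these lists had a Pearson correlation of 0.926 (exact permutation p = 0.0417) and a Spearman correlation of 0.486 (exact permutation p = 0.356), and another such correlation, within the 3 WT arrays, rests on too few arrays to be given. Without the 2 arrays farthest from the median the Pearson value was -0.585, so the relation rests on those arrays and does not decide. For the macrophage list a single array as the whole cause was argued against at camera's preset correlation, as its highest adjusted p with 1 array left out was 0.014, but without that array, WT replicate 3, the median shrank from -0.244 to -0.091, and WT replicate 2 (-0.213) lay among the KD arrays (-0.299 to -0.176). That array thus carried most of the shift, and with an estimated correlation over all 6 arrays the adjusted p was 0.497. For the interferon list a single array remained a candidate cause, as its adjusted p reached 0.93 without the same array.

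A second hypothesis was that DNA flanking the altered locus, carried along from the cells in which it was made, differs between KD and WT mice and changes genes near Slc18a3. Among the 50 genes on each side on chromosome 14, 1 in cardiomyocytes and 3 in hearts had an unadjusted p under 0.05 by limma. Their mean squared moderated t was 0.63 in cardiomyocytes and 0.96 in hearts. Of 17845 runs of neighbouring genes of this length, 89.4% had a value as high in cardiomyocytes and 68% in hearts, which argues against such an effect over this whole stretch. The neighbours with the smallest p were Grid1 at -0.28 in cardiomyocytes and Ghitm at -0.59 in hearts, both singled out after their values were seen.

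The 6 cardiomyocyte arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes at an adjusted p under 0.05, as did all 10. It gave 419 genes at an unadjusted p under 0.05, where all 10 gave as many and the highest other split gave 1635, and 6 lists, where 4 gave as many and the highest other gave 11. The highest other count of genes, several times the real one, points to a structure of these arrays, which was not examined. In hearts the real split gave 0 genes at an adjusted p under 0.05, 982 at an unadjusted p under 0.05 and 19 lists. The split by replicate number gave 8, 2171 and 2, and the remaining one 1, 747 and 4. The replicate number thus separated the heart arrays in more genes than the genotype did, and in fewer lists.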
